A study of Mus musculus with 6 samples.

How the data were processed

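RNA of 6 cultures of MA-10 cells was measured on Affymetrix arrays of the ST type, which read a transcript with many short probes summarised as a probe set. Per the labels, 3 biological replicates had received a control siRNA and 3 an siRNA against COUP-TFII, and the cells were transfected for 48 h. Partek 7.0 was used, per the submitters' processing notes. The methods of background correction, summarisation and normalization are not given in the sources used here, and no scanner files were used here.

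The deposited value table of the authors holds normalized log2 expression for 35556 probe sets, with values between 3.15 and 14.3. The log2 scale was read from the values, since differences of group means followed the log2 of the deposited ratios. The deposited annotation gives 26836 probe sets at least 1 gene symbol, of which 25454 have exactly 1 and 1382 have several, and 8720 have none. For 1224 probe sets only the symbol and no longer gene description was used here. Entrez ID or symbol matched the reference gene table (assembly GRCm38.p6, used for names only) for 22533 probe sets. Chromosomes and bands are those of the deposited annotation, which names no genome build, so no base positions are given.

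A deposited table of the authors gives for all probe sets a linear ratio of COUP-TFII siRNA over control siRNA, a signed fold (a score that is minus 1 over the ratio where the ratio is below 1) and an unadjusted p-value. The smallest design that fits the sums of squares in that deposited table has 4 groups and 12 arrays, and which arrays beyond the 6 used here entered it is not known. A further deposited table lists 334 changed probe sets, with p-values and ratios whose sums of squares fit 2 groups and 6 arrays as the smallest design. Every p-value in that deposited list is at or below 0.00995 and every fold is at least 1.30. The deposited ratios were not identical to the differences in the value table, with a mean absolute difference of 0.022 on the log2 scale over the list. All differences, errors and tests given for the 6 arrays come from the value table, and the authors' deposited list was only compared with them.

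Each probe set with a gene symbol was fitted with limma 3.58.1 (lmFit and eBayes with the default prior) in R 4.3.3, with the group as the only term, on all 6 arrays. A probe set was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 26836 probe sets, with no fold minimum. Changes are COUP-TFII siRNA minus control siRNA on the log2 scale, and standard errors (SE) are the moderated ones of limma. The number of arrays limits the precision. With 3 arrays against 3, an exact permutation test of a single gene cannot give a 2-sided p under 0.1.

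Before the data were examined, 33 gene lists, the rule for named genes and the alternatives of the sensitivity part were fixed, and a list had to have 5 measured members. Of the 847 different genes on the lists, 825 were found by symbol and 2 by an older or newer name, 18 lie only on probe sets shared with another gene and were left out, among them Insl3, and 2 have no probe set. A gene with several probe sets was represented by the brightest over all 6 arrays, among probe sets with exactly 1 symbol, which gave 24032 genes. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 33 lists. The same test with a correlation estimated from the 6 arrays was an alternative. A call lost there does not by itself show that the members of a list are correlated. Fry was also run, but it tests a list against no change and not against other genes. The text names Nr2f2 and 12 fixed genes of Leydig cells, steroid synthesis and COUP-TFII biology, where a probe set has that single symbol. It also names the 10 largest rises and the 10 largest falls among changed genes whose 2 groups did not overlap, leaving out predicted genes, small RNAs, pseudogenes and olfactory or vomeronasal receptors. From each list it takes up to 4 members with the smallest p, changed members first, and at most 2 where none changed. Further changed members named beside these were chosen after their values were seen. Some results for withheld genes are not reported here, though counts include them. No siRNA sequence was searched for effects on other transcripts.

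The fit was tested on simulated data with the means of the 26836 probe sets and 200 changed ones. Spreads were drawn from the fitted prior regardless of brightness, and genes were independent of each other. It recovered 24% of the probe sets changed 1.2-fold, 62% of those changed 1.3-fold, and 100% of those changed 1.5-fold or 2-fold. Of 153 calls, 10 were false, and 0 calls were made where nothing had been changed. In the list test 3 of 3 lists shifted by -0.2 were recovered with 1 false call. That shift is larger than the median of any list called here. Without correlated genes, the simulation cannot give the false call rate of camera on real lists. Alternatives covered dim probe sets, the probe sets tested, the normalization between arrays, the variance prior, array weights, the replicate number as a block, the threshold, the list test and leaving out each array. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.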

Results

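MA-10 cells are a mouse Leydig tumour line that makes steroids. They were used to ask which transcripts change after an siRNA against COUP-TFII, an orphan nuclear receptor encoded by Nr2f2. Gene expression was measured on 6 arrays, 3 from cells given a control siRNA and 3 from cells given an siRNA against COUP-TFII, 48 h after transfection. Values are normalized log2 expression as deposited, and array medians lay between 7.56 and 7.60. These medians were higher in COUP-TFII siRNA arrays (mean 7.595) than in control arrays (mean 7.565), without overlap. Replicates within a group correlated at r = 0.995 to 0.997 across probe sets, and arrays of different groups at 0.995 to 0.996, where probe sets are not independent replicates. The first principal component held 43.0% of the variance and separated the 2 groups.

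The Nr2f2 transcript itself fell by 0.63 on the log2 scale (SE 0.09, n = 3 per group), to 64.4% of the control level, with a limma adjusted p of 0.00802. The probe set 10564527, annotated to chromosome 7 band D1, read 8.98, 8.97 and 9.19 in the control arrays and 8.25, 8.42 and 8.56 in the COUP-TFII siRNA arrays. The groups did not overlap, and the exact permutation p was 0.1, the smallest that 3 against 3 arrays can give. Nr2f1, which encodes the close relative COUP-TFI, differed by 0.03 (SE 0.05) and was not called (adjusted p = 0.807). Its probe set was dim, at 6.64 in control and 6.67 in COUP-TFII siRNA arrays (percentile 34.7 of mean expression). Few probe sets that dim were called. Nr5a1, the gene of the steroidogenic master regulator SF-1, differed by -0.02 (SE 0.05, adjusted p = 0.898).

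**Figure D1:**
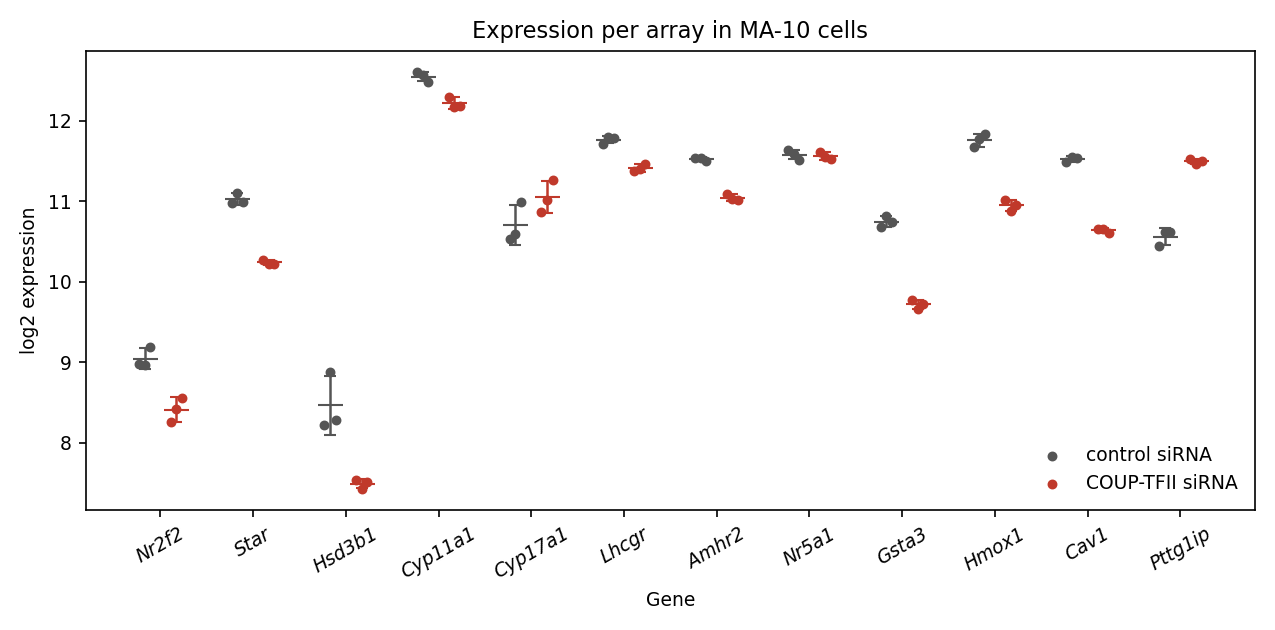
Normalized log2 expression of 12 genes in control siRNA (grey) and COUP-TFII siRNA (red) arrays, with a point per array, the mean as a horizontal dash and the SD (n = 3) as error bars. Nr2f2 fell from a mean of 9.05 to 8.41 and Star from 11.03 to 10.24, while Nr5a1 stayed at 11.58 and 11.56 and Cyp17a1, at 10.71 and 11.05, was not called.

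In COUP-TFII siRNA cells, 783 probe sets were lower and 426 were higher, so that 1209 of 26836 changed and 35.2% of the changed ones rose. Falls were also the larger changes among these probe sets with a gene symbol. At least 1.5-fold changes numbered 52 falls and 9 rises, and at least 2-fold changes 6 falls and 0 rises. Probe sets without a symbol did not show more falls than rises when all were fitted together, and this split was not tested. There, 36 were higher and 28 lower, with changes up to 1.55 and down to -0.94. The median change among the 1209 was 1.24-fold and the smallest was 1.14-fold. At an unadjusted p under 0.05, 5172 probe sets differed. Centring every array on its median gave 308 higher and 1184 lower probe sets, which puts the share of rises at 20.6%.

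Taking the brightest probe set of each gene, the largest fall was that of Cd109, a membrane-anchored co-receptor that restrains TGF-beta signalling, by 1.17 (SE 0.05, adjusted p = 8.7e-05), to 44.4% of control. The kinase gene Stk32a fell by 1.04 (SE 0.12) and the glutathione transferase gene Gsta3 by 1.02 (SE 0.05). Lgmn, which encodes the lysosomal protease legumain, fell by 0.95 (SE 0.06) and Tlcd2 by 0.90 (SE 0.06). Cav1, the main structural protein of caveolae, fell by 0.89 (SE 0.05), pyruvate carboxylase (Pcx) by 0.85 (SE 0.08) and the iron exporter Slc40a1 by 0.84 (SE 0.07). Hsd3b1, described with the steroid genes, is also among the 10 largest falls.

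Among rises, Pttg1ip, a binding partner of securin, came first with 0.93 (SE 0.06, adjusted p = 0.000755), or 191% of control. Man2a1, a mannosidase of the Golgi that trims N-glycans, rose by 0.75 (SE 0.06), and Mybpc3, known from heart muscle sarcomeres, by 0.72 (SE 0.05). The transcription factor gene E2f5 rose by 0.67 (SE 0.06). Nagpa, whose product exposes the mannose 6-phosphate tag of lysosomal enzymes, rose by 0.67 (SE 0.05). Hpse, encoding heparanase, rose by 0.65 (SE 0.05), the kinase gene Uhmk1 by 0.62 (SE 0.05) and the lysosomal cystine exporter Ctns by 0.60 (SE 0.08). The growth factor receptor gene Fgfr4 rose by 0.59 (SE 0.05) and the transcription factor gene Maf by 0.57 (SE 0.05).

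**Figure D2:**
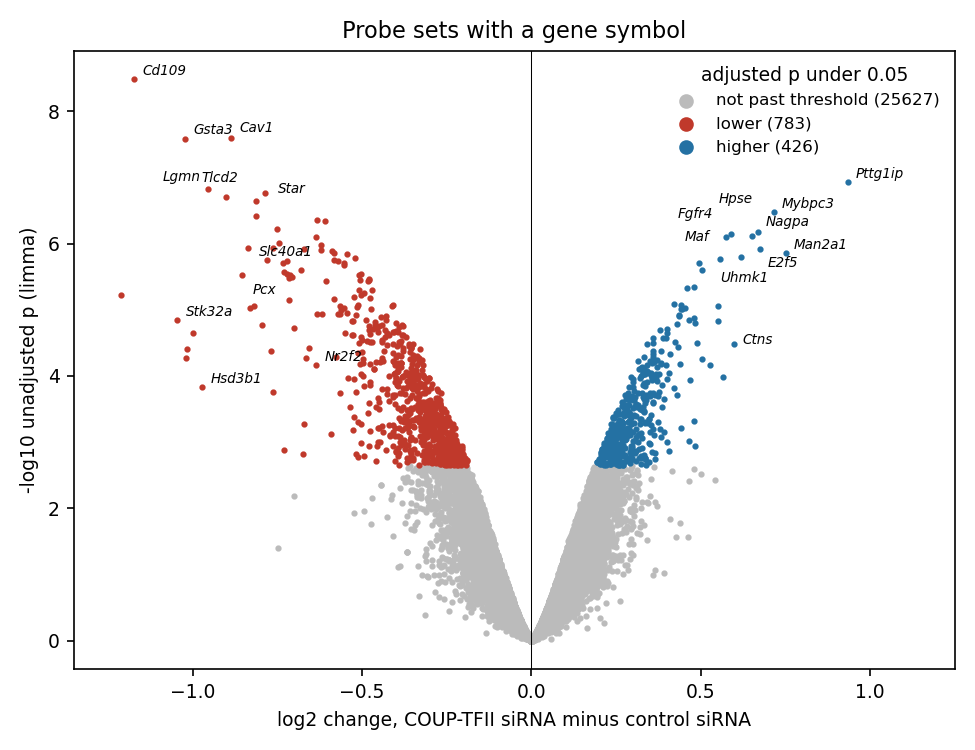
Log2 change (COUP-TFII siRNA minus control siRNA, horizontal) against -log10 of the unadjusted limma p (vertical) for the 26836 probe sets with a gene symbol, with 783 lower ones in red, 426 higher ones in blue and the others in grey. The falls reach further from 0 than the rises, with Cd109 at -1.17 and Pttg1ip at 0.93.

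Genes of steroid synthesis fell. Of 28 measured steroidogenic enzymes and carriers, 9 fell and 0 rose (14 and 0 adjusted over the list alone), and 22 lay below 0. Star, whose product brings cholesterol into the mitochondrion, the rate-limiting step of acute steroid synthesis, fell by 0.78 (SE 0.05, adjusted p = 0.000755), to 58.0% of control. Cyp11a1, the side-chain cleavage enzyme that makes pregnenolone, fell by 0.33 (SE 0.06, adjusted p = 0.0168), and Fdx1, its electron donor, by 0.38 (SE 0.04). Hsd3b1, which makes progesterone from pregnenolone, fell by 0.97 (SE 0.15, adjusted p = 0.0117), from 8.47 ± 0.37 to 7.49 ± 0.06 (SD, n = 3), with control replicate 2 highest at 8.89. Its paralog Hsd3b6 changed by -0.50 (SE 0.10), and whether probes of these close paralogs cross-hybridise was not tested here. Akr1c18 and Akr1c14, reductases of progesterone and of 3-ketosteroids, fell by 0.77 (SE 0.10) and by 0.73 (SE 0.07). Cyp17a1, needed for androgens, differed by 0.34 (SE 0.13) in the other direction and was not called (adjusted p = 0.201). With the replicate number as a block it passed as a rise (limma adjusted p = 0.0389). The list was lower than other genes by camera (adjusted p = 5.07e-08), but not with an estimated correlation (adjusted p = 0.127). That estimate was 0.00685, below the preset 0.01, so a higher correlation between members does not account for the lost call. Without COUP-TFII siRNA replicate 2, adjusted p was 0.0651 for Hsd3b1, 0.0798 for Cyp11a1 and 0.123 for Hsd3b6, and without COUP-TFII siRNA replicate 3 it was 0.0651 for Cyp11a1.

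Leydig cell markers and hormone receptors fell as well, 10 of 23 measured with 0 rises (11 and 5 adjusted over the list alone), though 13 lay below 0 and 5 of the 10 are not receptors but Star, Hsd3b1, Cyp11a1 and the inhibin genes Inha and Inhba. Lhcgr, the receptor of luteinizing hormone, fell by 0.35 (SE 0.05, adjusted p = 0.00858), to 78.2% of control. Amhr2, the type 2 receptor of anti-Mullerian hormone, fell by 0.48 (SE 0.05, adjusted p = 0.00181) and the prolactin receptor gene Prlr by 0.51 (SE 0.05), with a second probe set at -0.72 (SE 0.07). Inha, the alpha subunit of inhibin, fell by 0.56 (SE 0.06) and Inhba, the beta A subunit, by 0.25 (SE 0.05). Without COUP-TFII siRNA replicate 2, adjusted p for Inhba was 0.0836, and Igf1r and Ptch1 were the other falls, at -0.26 (SE 0.05) and -0.22 (SE 0.05). Camera gave an adjusted p of 0.000703 for this list (adjusted p = 0.29 with an estimated correlation). Its median of -0.04 lay inside the range of random lists of equal expression, at percentile 3.59.

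Cholesterol synthesis was lower, with 5 falls and 0 rises among 25 members (13 and 0 adjusted over the list alone). Fdft1, or squalene synthase, changed by -0.26 (SE 0.05) and Insig1 by -0.27 (SE 0.04). The mevalonate kinases Mvk and Pmvk each changed by -0.30 (SE 0.07 and 0.06). Camera gave an adjusted p of 7.62e-09, and the call was lost with the estimated one (adjusted p = 0.29 with an estimated correlation). Another split of the 6 arrays gave this list a camera p of 1.89e-09, close to the 6.93e-10 of the real split. Each of these 4 genes missed the threshold without COUP-TFII siRNA replicate 2, with adjusted p = 0.0831 for Fdft1, 0.124 for Mvk, 0.113 for Pmvk and 0.0637 for Insig1. Genes of cholesterol uptake, storage and efflux were not shifted as a list (adjusted p = 0.431), with 3 falls and 0 rises among 20 (4 and 1 adjusted over the list alone). These 3 were the lipid droplet protein Plin2 at -0.28 (SE 0.05), the efflux pump Abca1 at -0.29 (SE 0.05) and the HDL receptor Scarb1 at -0.19 (SE 0.05, adjusted p = 0.0499). None of them passed without COUP-TFII siRNA replicate 2, where adjusted p was 0.0776 for Plin2, 0.0811 for Abca1 and 0.161 for Scarb1.

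Camera with the preset correlation gave its smallest p to glutathione and antioxidant defence, in which 14 of 31 measured genes fell and 0 rose (19 and 1 adjusted over the list alone), and 29 lay below 0. Besides Gsta3, heme oxygenase (Hmox1) fell by 0.81 (SE 0.06, adjusted p = 0.00102) and the quinone reductase Nqo1 by 0.78 (SE 0.07). Gsta2 fell by 0.72 (SE 0.06) and the cystine importer Slc7a11 by 0.83 (SE 0.09). Gclc and Gclm, the subunits of the enzyme that starts glutathione synthesis, fell by 0.22 (SE 0.05) and by 0.32 (SE 0.06). Camera gave an adjusted p of 8.04e-16 (adjusted p = 0.279 with an estimated correlation).

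DNA replication and S phase genes were lower, with 4 falls and 0 rises among 33 (12 and 0 adjusted over the list alone), and 31 lay below 0. The clamp loader subunit Rfc4 fell by 0.33 (SE 0.05), the replicative helicase factors Gins1 and Gins2 by 0.40 (SE 0.06) and by 0.36 (SE 0.08), and cyclin E1 (Ccne1) by 0.28 (SE 0.04). Camera gave an adjusted p of 5.87e-09 (adjusted p = 0.306 with an estimated correlation). Without COUP-TFII siRNA replicate 2, adjusted p was 0.13 for Gins2 and 0.0612 for Ccne1. Among 32 G2/M and mitosis genes, 2 fell and 0 rose (4 and 0 adjusted over the list alone), Hmmr by 0.38 (SE 0.07) and cyclin B2 (Ccnb2) by 0.25 (SE 0.05), and the list was lower by camera (adjusted p = 1.76e-05, and adjusted p = 0.68 with an estimated correlation). Without that same replicate, adjusted p was 0.0727 for Hmmr and 0.136 for Ccnb2. Of 45 replication-dependent histone genes none was called, with 0 falls and 0 rises over all genes and over the list alone, while 43 lay below 0, and camera placed the list lower (adjusted p = 0.000103, and adjusted p = 0.843 with an estimated correlation). Hist1h2bc differed by -0.22 (SE 0.06) and Hist1h2ae by -0.19 (SE 0.05). Hist1h2bc passed without control siRNA replicate 1 (adjusted p = 0.0491) and under 6 other alternatives (0.0124 to 0.0497), and Hist1h2ae under 4 (0.0298 to 0.0382), among them median centring for each.

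Metabolic lists were lower too. Fatty acid synthesis and oxidation had 5 falls and 0 rises among 31 (9 and 1 adjusted over the list alone), with camera adjusted p = 0.000703 (adjusted p = 0.29 with an estimated correlation). Acacb, a carboxylase that makes malonyl-CoA, fell by 0.39 (SE 0.05) and Cpt2, which brings acyl groups into mitochondrial oxidation, by 0.34 (SE 0.05). Ehhadh and Acadvl, enzymes of beta-oxidation, changed by -0.38 (SE 0.07) and -0.27 (SE 0.06), and without COUP-TFII siRNA replicate 2 their adjusted p was 0.0945 and 0.13. Of 25 hypoxia and glycolysis genes, P4ha1, a collagen prolyl hydroxylase, was the 1 that fell, by 0.32 (SE 0.05), with 0 rises (6 and 0 adjusted over the list alone), and camera gave an adjusted p of 2.24e-05 (adjusted p = 0.627 with an estimated correlation). P4ha1 had an adjusted p of 0.0518 without COUP-TFII siRNA replicate 2. Among 40 genes of oxidative phosphorylation there were 0 calls in either direction, over all genes and over the list alone, though 36 lay below 0, and camera gave an adjusted p of 3.02e-05 (adjusted p = 0.398 with an estimated correlation). The respiratory chain genes Ndufs3 and Uqcrc2 differed by -0.15 (SE 0.05) and -0.16 (SE 0.05), and passed among brighter probe sets (adjusted p = 0.033 and 0.0373) and with an intensity trend in the prior (0.0218 and 0.0178). For G2/M, histones, hypoxia and oxidative phosphorylation, at least 1 other split of the same 6 arrays gave as small a camera p as the split by siRNA.

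**Figure D3:**
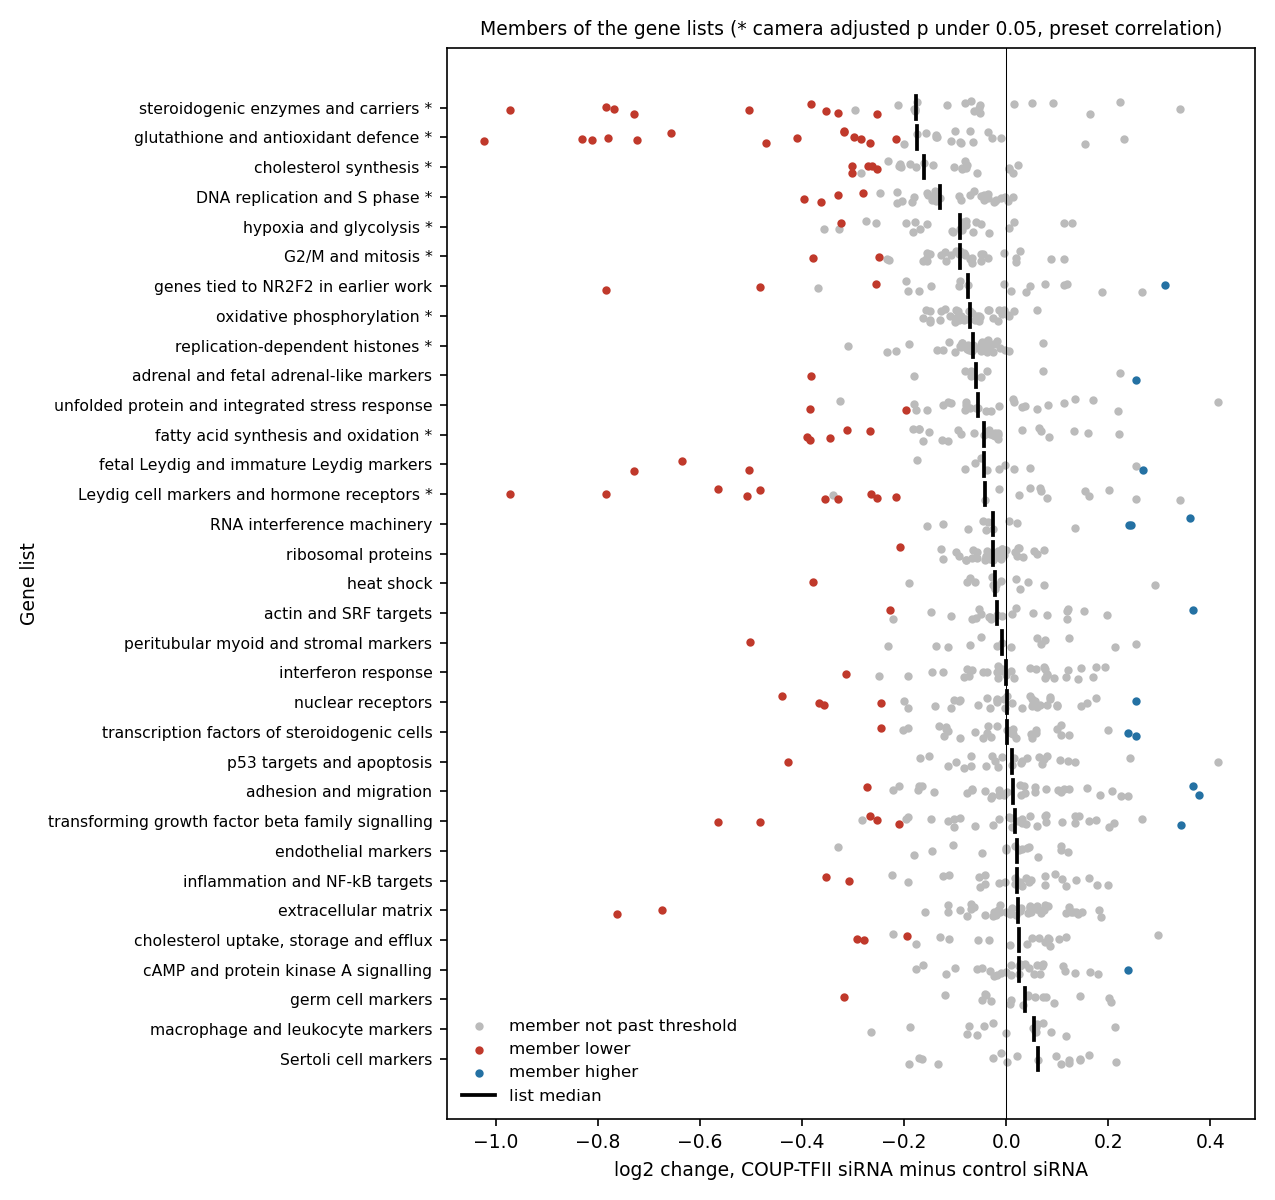
Log2 change (COUP-TFII siRNA minus control siRNA) of each measured member of the 33 gene lists, with members that fell in red, members that rose in blue, other members in grey and the list median as a black bar. The 10 lists marked with an asterisk passed camera with the preset correlation and have medians below 0, from -0.04 to -0.18, and no list passed with an estimated correlation.

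Transcription factors of steroidogenic cells were not shifted (camera adjusted p = 0.741), with 2 rises and 1 fall among 31 (2 and 2 adjusted over the list alone). Nr0b1, which encodes the repressor DAX-1, rose by 0.25 (SE 0.05) and Creb1 by 0.24 (SE 0.05), and Fosl1 fell by 0.25 (SE 0.06). Without COUP-TFII siRNA replicate 2, adjusted p for these was 0.0704, 0.131 and 0.158, and after median centring it was 0.0569 for Creb1. Nuclear receptors were not shifted either (adjusted p = 0.67), with 4 falls and 1 rise among 39 (4 and 1 adjusted over the list alone). Nr0b2, encoding the corepressor SHP, fell by 0.44 (SE 0.06), the thyroid hormone receptor gene Thra by 0.37 (SE 0.06) and the estrogen receptor gene Esr1 by 0.24 (SE 0.05), and without the same replicate adjusted p was 0.0612 for Thra and 0.121 for Esr1. Of 21 genes tied to COUP-TFII in earlier work, Star, Amhr2 and Hey2 fell and Jag1 rose (4 falls and 2 rises adjusted over the list alone), and the list was not called (adjusted p = 0.0828, but 0.0487 without control siRNA replicate 3). Hey2 changed by -0.26 (SE 0.06) and the Notch ligand gene Jag1 by 0.31 (SE 0.07), and without COUP-TFII siRNA replicate 2 their adjusted p was 0.139 and 0.15. Jag1 also missed the threshold under each of 3 other normalizations, with adjusted p = 0.0523 after median centring, 0.0541 after quantile and 0.0513 after cyclic loess normalization.

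The TGF-beta family list was not shifted (adjusted p = 0.67), with 5 falls and 1 rise among 38 (7 and 3 adjusted over the list alone). Beside Amhr2, Inha and Inhba, the falls were Id1 at -0.21 (SE 0.04) and Tgfbr1 at -0.27 (SE 0.06), and the activin receptor gene Acvr1b rose by 0.34 (SE 0.05), with adjusted p = 0.052 without COUP-TFII siRNA replicate 2. Extracellular matrix (2 falls and 0 rises among 48, adjusted p = 0.875) held Fbn1, or fibrillin 1, at -0.76 (SE 0.12) and Col6a3 at -0.67 (SE 0.15), the latter with adjusted p = 0.0973 without that replicate and 0.0706 with array weights, and the counts were the same adjusted over the list alone. In adhesion and migration (2 rises and 1 fall among 36, adjusted p = 0.829, 5 and 4 adjusted over the list alone), the integrin gene Itgav rose by 0.38 (SE 0.06) and the focal adhesion gene Vcl by 0.37 (SE 0.05), and the guidance receptor gene Robo1 fell by 0.27 (SE 0.05). Their adjusted p without COUP-TFII siRNA replicate 2 was 0.0533, 0.0565 and 0.111. Actin and SRF targets (adjusted p = 0.937) had 1 rise, Vcl, and 1 fall, Tpm2 at -0.23 (SE 0.05), among 23 (2 and 1 adjusted over the list alone), and without that replicate adjusted p for Tpm2 was 0.123. Among 30 genes of cAMP and protein kinase A signalling, Creb1 was the 1 rise and there were 0 falls, also adjusted over the list alone (camera adjusted p = 0.713). In the RNA interference machinery, 3 of 13 rose and 0 fell (3 and 1 adjusted over the list alone, adjusted p = 0.741). These were Tnrc6a, by 0.36 (SE 0.05), and the Argonaute genes Ago1, by 0.25 (SE 0.05), and Ago2, by 0.24 (SE 0.05), and without COUP-TFII siRNA replicate 2 adjusted p was 0.0675 for Ago1 and 0.124 for Ago2, and after median centring it was 0.0563 for Ago2.

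Stress and immune lists were not shifted. The p53 targets and apoptosis list (adjusted p = 0.829) had 1 fall, the cell cycle inhibitor Cdkn1a at -0.43 (SE 0.07), and 0 rises among 27 (2 and 2 adjusted over the list alone). The unfolded protein and integrated stress response (adjusted p = 0.137) had 2 falls, Atf3 at -0.38 (SE 0.08) and Creld2 at -0.20 (SE 0.04), and 0 rises among 29 (4 and 2 adjusted over the list alone), and passed without control siRNA replicate 1 (adjusted p = 0.0271). Heat shock (adjusted p = 0.493) had 1 fall, Hspa4l at -0.38 (SE 0.05), among 15, also adjusted over the list alone. The interferon response (adjusted p = 0.937) had 1 fall, Ifi35 at -0.31 (SE 0.06), and 0 rises among 35, and inflammation and NF-kB targets (adjusted p = 0.788) had 2 falls, Lif at -0.35 (SE 0.06) and Nfkbiz at -0.31 (SE 0.05), and 0 rises among 28, with the same counts adjusted over each list alone. Ribosomal proteins (adjusted p = 0.0787) had 1 fall and 0 rises among 36, and 0 calls adjusted over the list alone. Without COUP-TFII siRNA replicate 2, adjusted p was 0.0683 for Cdkn1a, 0.133 for Atf3, 0.154 for Creld2, 0.0727 for Ifi35, 0.0613 for Lif and 0.0856 for Nfkbiz. The ribosomal list passed after median centring (adjusted p = 0.0314), with an intensity trend in the prior (0.0465, also with a robust prior), without control siRNA replicate 1 (0.0271) and without control siRNA replicate 3 (0.0364).

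Markers of other cell types of the testis were not shifted. Sertoli cell markers had 0 calls among 17 (adjusted p = 0.67), with Sox9 at 0.21 (SE 0.08) and Ctsl at -0.19 (SE 0.05). Macrophage and leukocyte markers had 0 calls among 18 (adjusted p = 0.829), with Ptprc at 0.21 (SE 0.06) and H2-Ab1 at -0.19 (SE 0.06), and endothelial markers 0 among 16 (adjusted p = 0.829), with Sox18 at -0.33 (SE 0.09) and Cdh5 at -0.15 (SE 0.06). Each of these 3 lists also had 0 calls adjusted over the list alone. Sox18 passed without control siRNA replicate 3 (adjusted p = 0.0465), among brighter probe sets (0.0367) and with an intensity trend (0.0324, or 0.0293 with a robust prior), and Ctsl passed in these last 3 settings (0.0203, 0.00605 and 0.00577) and after median centring (0.0373). Peritubular myoid and stromal markers (adjusted p = 0.676) had 1 fall among 15, Ly6a at -0.50 (SE 0.09), and germ cell markers (adjusted p = 0.701) had 1 fall among 18, Ddx4 at -0.32 (SE 0.06), with the same counts adjusted over the list alone, and without COUP-TFII siRNA replicate 2 their adjusted p was 0.0987 and 0.0916. Adrenal and fetal adrenal-like markers (adjusted p = 0.428) had 1 fall, Fdx1, and 1 rise, Nr0b1, among 10, also adjusted over the list alone. Of 14 fetal and immature Leydig markers (adjusted p = 0.0787, but 0.0465 with an intensity trend in the prior), 3 fell, namely Nr2f2 itself, Akr1c14 and Hsd3b6, and Crhr1 rose by 0.27 (SE 0.05, adjusted p = 0.0683 without COUP-TFII siRNA replicate 2), with 4 falls and 2 rises adjusted over the list alone. Median, mean and test differed in sign for 11 of the 23 lists that were not called and for 0 of the 10 that were.

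All 261 probe sets with a gene symbol in the authors' deposited table of changed genes, 204 lower and 57 higher, were called here in the same direction. That table compares the same 2 groups, and its sums of squares fit 6 arrays as the smallest design, so it is taken as no independent evidence. Another 948 probe sets were called here, with no fold minimum, and are not in it. At the limits of that table, an unadjusted p under 0.01 and at least 1.3-fold, 323 probe sets with a symbol passed here, 236 of them in the table. Leaving out any array lowered the count of changed probe sets from 1209 to 737 (without control siRNA replicate 1), 708 (without control siRNA replicate 2), 475 (without control siRNA replicate 3), 440, 306 and 507 (without COUP-TFII siRNA replicates 1, 2 and 3). Of 82 genes taken by the naming rule and past the threshold, 39, among them Nr2f2, Star, Lhcgr, Amhr2, Gsta3, Hmox1, Cav1 and Cd109, stayed past it whichever array was left out, and 43 did not. All 43 missed it without COUP-TFII siRNA replicate 2, and many of them without another array too, with 25, 19 and 31 missing it without control siRNA replicates 1, 2 and 3 and with 33 and 30 missing it without COUP-TFII siRNA replicates 1 and 3.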

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

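The result below lies in data that the comparisons do not use, and it was looked for after the comparison had been made. Of 8720 probe sets to which the annotation gives no gene symbol, 64 changed when all probe sets were fitted together with limma, 36 of them higher and 28 lower. That is 0.734% of them, against 1.39% of the named probe sets in the same fit. The changes reached 1.55 and -0.94 on the log2 scale, and 41 of the 64 are also in the authors' deposited table of changed genes.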

How the results depend on the processing

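All alternatives were fixed before the data were examined. Compared with 1209 changed probe sets (426 higher, 783 lower), the count was 2375 (923 and 1452) among probe sets at or above the median brightness, 436 (145 and 291) over all probe sets, 2132 (815 and 1317) with an intensity trend in the prior, 2172 (833 and 1339) with a trend and a robust prior, and 156 (61 and 95) with no moderation. Median centring gave 1184 lower probe sets. Array medians were higher in the COUP-TFII siRNA group, so centring lowered every change by the same amount. The median change of all tested went from 0.0146 to -0.0156. The cause was not tested for the other counts. Stricter or looser thresholds gave, by construction, 295 (83 and 212) at adjusted p under 0.01, 2222 (891 and 1331) at adjusted p under 0.1, 61 (9 and 52) with a 1.5-fold minimum, and 63 (9 and 54) at unadjusted p under 0.05 with that minimum. Leaving out 1 array, which leaves fewer degrees of freedom, gave between 306 and 737 changed (96 to 240 higher, 210 to 518 lower). No probe set called in the comparison changed sign under any setting in which it was tested. That was fixed in advance for most settings, since the groups did not overlap for any of the 1209. Only the other normalizations could have changed a sign. With the replicate number as a block, 711 probe sets changed (227 and 484), 644 of them among the 1209, and of the uncalled named genes Cyp17a1 (adjusted p = 0.0389) and Sox18 (0.0414) passed with that block, while 20 named genes lost their call. Whether the numbers pair the arrays is not stated in the labels and stays open. Deviations of same-numbered arrays correlated at 0.108, -0.048 and 0.172, and 3 of 6 arrays correlated best with their own number. Nr2f2 stayed at -0.63 with no moderation but had an adjusted p of 0.112, within a range of 0.000969 to 0.112 over its alternatives, and passed under the others. The share of the deposited list that passed was 24.5% with no moderation and at least 80.8% otherwise. Of 33 gene lists, 10 passed with the preset correlation, 0 with an estimated correlation (camera, 5 at unadjusted p under 0.05), 8 with fry's directional test and 31 with its mixed test, which ask about any change and not about a difference from other genes, and 10 to 12 under the other settings. G2/M, histones, hypoxia and oxidative phosphorylation were the called lists that fry did not pass, and the genes tied to COUP-TFII (0.0147) and adrenal markers (0.0105) passed there and not by camera. Of 95 genes taken by the naming rule, 19 were past an adjusted p of 0.05 under all alternatives other than the changed thresholds, which were not part of that count. With no moderation 60 calls of other named genes than Nr2f2 were lost, over all probe sets 36, and without COUP-TFII siRNA replicate 2 43, and no call of a named gene reversed. Per-sample values of the deposited table of all genes were not run as an alternative, because the table as used here has no per-sample columns. Brightness limits what was seen: the dimmest 5368 probe sets held 12 rises and 7 falls.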

Other observations

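The 8 gene lists of this part were written after the comparison had been seen and before the lists were tested. The changes of their single members had by then been computed, so the lists are not independent of these data. The other splits per gene list were a test chosen only after the result was seen. Genes that handle aldehydes and carbonyls were lower, with 5 falls and 0 rises among 29, but this list shares Akr1b3, Cbr1 and the falls Ephx1 and Akr1b8 with the NFE2L2 targets below. Adh1, an alcohol dehydrogenase, fell by 0.52 (SE 0.06), Aldh5a1, the succinate semialdehyde dehydrogenase, by 0.31 (SE 0.06) and Adh7 by 0.29 (SE 0.05). Camera gave an adjusted p of 0.000503 over the 8 lists (adjusted p = 0.199 with an estimated correlation). Genes of Golgi glycosylation other than Man2a1, which rose and was left off, were not called as a list (adjusted p = 0.207), with 4 falls and 1 rise among 32, such as Galnt2 at -0.43 (SE 0.05).

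Iron handling genes other than Slc40a1 and Hmox1, which fell and were left off the list (adjusted p = 0.884), held 1 fall, the macrophage-type metal transporter Slc11a1 at -0.47 (SE 0.05), and 2 rises, Bdh2 at 0.47 (SE 0.10) and the ferritin cargo receptor Ncoa4 at 0.27 (SE 0.06), among 22. Caveolae genes other than Cav1 had 0 calls among 8 (limma, adjusted p = 0.207 for the list). Members of the PI3K and AKT pathway (adjusted p = 0.884) had 1 rise, Foxo1 at 0.27 (SE 0.05), and 2 falls, the AKT phosphatase gene Phlpp2 at -0.34 (SE 0.05) and Irs1 at -0.27 (SE 0.06), among 27. FOXO targets (adjusted p = 0.293) had 2 falls, Cat and Gabarapl1, and 0 rises among 29.

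A lower NFE2L2 programme, that of the transcription factor NRF2, is a candidate explanation for the fall of the antioxidant list. Of 26 further NFE2L2 targets, none of them on the fixed lists, 25 lay below 0, 6 fell and 0 rose, among them Blvrb at -0.54 (SE 0.06), Aox1 at -0.50 (SE 0.05) and Pir at -0.43 (SE 0.06). Their median was -0.13 (95% bootstrap interval over genes -0.22 to -0.095), with a camera p of 2.07e-11 (adjusted p = 0.0603 with an estimated correlation). That interval resamples genes and not arrays, and the other splits of the arrays were not run for these targets. Variation between the arrays other than the siRNA therefore stays open for them. Probe sets shared between glutathione transferase paralogs do not account for the fall, since without those genes the remaining members had a median of -0.17. Camera with the preset correlation gave these 20 genes a p of 2.17e-13. An estimated correlation, with which the whole list had an adjusted p of 0.279, was not run for them. A normalization that depends on brightness is argued against too, because 0% of 10000 random lists matched on mean expression had a median as low, and what lowered the NFE2L2 targets was not tested.

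The 9 other gene lists that camera placed lower were set against brightness-dependent normalization and against variation between the arrays. Brightness-dependent normalization is argued against for most, as 8 of the 9 had a median below the lowest 2.5% of matched random lists, Leydig cell markers being the exception at percentile 3.59. Variation between the arrays other than the siRNA stays open for all 9, and for the antioxidant list too. For that list another split gave a camera p of 2.37e-07, against 2.44e-17 by siRNA. For 4 of the 9, G2/M, histones, hypoxia and oxidative phosphorylation, another split of the 6 arrays gave as small a camera p. For histones that p was 1.03e-13, against 2.5e-05 by siRNA, and for the other 5 the siRNA split had the smallest p, though 10 splits cannot give a share under 0.05.

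A rise of lysosomal genes as a group was tested because Nagpa, Hpse and Ctns are among the 10 highest, while Lgmn, also lysosomal, is among the 10 lowest, and these 4 were left off the list. Of 58 further lysosomal genes, 6 rose and 3 fell. The median of the 58 was 0.026 (95% bootstrap interval over genes -0.016 to 0.065), which leaves it open whether the group moved. Camera gave these 58 genes a p of 0.22. Slc17a5, the sialic acid exporter, rose by 0.36 (SE 0.04), the sialidase gene Neu1 by 0.34 (SE 0.05) and the glucosidase gene Gaa by 0.39 (SE 0.07). Ids, the iduronate sulfatase gene, fell by 0.45 (SE 0.07) and the cathepsin gene Ctsh by 0.36 (SE 0.05).

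The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The split by siRNA gave 1209 changed probe sets by limma, which 1 of 10 splits reached, itself, and the highest other split gave 0 (2045 at an unadjusted p under 0.05, against 5172). Every other split mixes the siRNA groups, so an siRNA effect adds to its spread and lowers its count. Each also holds part of the siRNA contrast, so its lists need not come from other variation alone. The siRNA split gave 10 gene lists by camera with the preset correlation, which 3 of 10 splits reached, itself included, and the highest other split gave 10.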
